A study of Rattus norvegicus with 84 samples.

How the data were processed

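RNA was measured in CA1, CA3 and the dentate gyrus (DG) of 28 male F344 rats, 12 young (5 months) and 16 middle-aged (12 months), 84 libraries in all. Per the labels, RNA came from 1 hemisphere, was selected by polyA, fragmented with RNase III and made into libraries with an Ion Total RNA-seq kit. The submitters' processing notes name STAR 2.5.3a, Partek and DESeq2 3.5 with build rn6, without their order or settings. The gene annotation, the filter on genes and the strand are not given in the sources used here. Each subregion has its own table, with 15553 genes in CA1, 15706 in CA3 and 15374 in the DG.

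The deposited values are a signal that the file names call normalized counts. Each library's values were whole multiples of 1 step, within 0.1 of a whole read for 100% of values up to 1000 reads, so they are gene counts divided by 1 size factor per library, and whole reads were recovered by undoing it. Recovered reads ranged from 14.4 to 23.4 M per library. The labels name ERCC spike-ins, but the tables hold 0 spike-in genes, so a planned rescaling by them was not run. Of the symbols, 84.0% in CA1 and 84.1% in CA3 and the DG were found among 47357 genes of the GRCr8 annotation, which differs from rn6, so no coordinates are given. For CA3, 1 of the columns bears an animal number without the subregion, and it was assigned to that animal's CA3 library, since the other columns of the table are all CA3.

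The groups, the main tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes with a value of at least 10 in at least 12 of 28 libraries were tested on log2 of the value plus 1 with limma 3.58.1 (empirical Bayes with a trend, 2-sided) in R 4.3.3. The p values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. This left 14685 genes in CA1, 14893 in CA3 and 14526 in the DG. The average over subregions used the mean of a rat's 3 log2 values, and differences of the age effect used the difference within each rat, paired by the animal in the titles. The correlation of libraries of the same rat in a joint fit was 0.127 for the DG and CA1, 0.122 for the DG and CA3 and 0.0928 for CA1 and CA3. That fit had no term for the run of animal numbers, and libraries of different rats were not paired for comparison. These values therefore do not check the pairing.

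Gene lists, 33 in number, were tested with camera at a preset correlation of 0.01 and at least 5 tested genes, adjusted over 96 tests. A list that no test called was not given a direction. The named genes are, per subregion and direction, the 8 with the smallest p and the 4 further ones with the largest change among called genes with a mean of at least 10, up to 4 members of each list with the smallest p, the 6 smallest p per direction for the average and for each difference, and the subregion markers. Members named in the text were taken from these. Some genes that the rule names are not reported here, but they stay in every test and count.

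On simulated data, the tests recovered 79.1% of genes changed 1.5-fold in CA1, 83.6% in CA3 and 91.0% in the DG, but 23.9%, 41.8% and 25.4% at 1.2-fold. For differences between subregions the shares at 1.5-fold were 71.6%, 62.7% and 65.7%. There were 1 to 8 false calls per comparison, and a shifted list was called in each subregion with 0 other lists. The simulated genes were drawn independently, without correlation between genes and without differences between runs. These rates need not hold in the real data, and the simulation cannot tell how often the tests call falsely there.

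The alternatives chosen in advance were pseudocounts of 0.5 and 5, no filter, a minimum of 50, rescaling by TMM or median of ratios, quantile normalization, robust moderation, array weights, a minimum fold of 1.2, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, a term for the run of animal numbers, each run alone, markers of other subregions as a covariate, leaving out each rat, fits without the rat or with it as a random block, an estimated correlation and fry. Chosen after the data were seen were a fit without the 3 libraries per subregion farthest from their group, the permutation of rats for lists (100000 permutations), the spread and single-rat fits of named genes, and the analyses of gene length, mitochondrially encoded genes and symbol families. The number of far libraries was first planned as 2 and set to 3 after the deviations were viewed, and only the latter was run. Other splits of the rats (100, the real one included) used a fixed seed. No library was left out of the main tests.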

Results

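Gene expression was measured by RNA sequencing in 84 libraries from 28 male F344 rats, an inbred strain used in ageing research. Each rat gave 1 library from CA1, 1 from CA3 and 1 from the dentate gyrus (DG), the 3 main subregions of the hippocampus, taken from a single hemisphere. The rats were young (5 months, 12 rats) or middle-aged (12 months, 16 rats), and the title of the series names age-related change in spatial pattern separation, the ability to tell similar places apart. Behavioural scores were not analysed here. Reads per library ranged from 14.4 to 23.4 M in CA1 (median 17.6), from 15.7 to 21.8 M in CA3 (median 18.5) and from 14.9 to 21.8 M in the DG (median 17.8). No 2 libraries of a subregion agreed within sampling noise. The animal numbers fall into 2 runs, the first with 6 young and 10 middle-aged rats and the second with 6 of each. In each run the ages hold separate blocks of numbers, and the labels do not call these batches. Counts of genes, called lists and the named genes of each subregion were therefore also compared within each run. Between runs, rats of the same age differed in 2666 genes in young CA1, the most, and in 97 in the middle-aged DG, the fewest. Within a run, a difference between blocks cannot be told apart from age in any subregion. Mitochondrially encoded genes took 11.5 ± 1.81% of reads in middle-aged and 8.54 ± 2.43% in young CA1 (SD, n = 16 and 12), 9.04 ± 1.36% and 7.59 ± 1.56% in CA3, and 7.96 ± 1.26% and 7.06 ± 2.64% in the DG.

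Genes known to mark each subregion were read first, as a check of the dissection. Wfs1, a CA1 pyramidal cell marker, had a median normalized read count of 26386 in CA1, 4844 in CA3 and 3320 in the DG. Cpne4 and Grik4, known from CA3, had medians of 7827 and 3095 there, against 769 and 627 in CA1 and 4238 and 2071 in the DG. Prox1, the transcription factor of dentate granule cells, had medians of 3511 in the DG, 628 in CA1 and 720 in CA3, and C1ql2 had 6779, 900 and 764. The median was highest in the named subregion for 10 of 10 CA1 markers, 10 of 13 CA3 markers (Coch, Cdh24 and Trhr were the exceptions) and 12 of 12 DG markers. The mean of each marker set was highest in its own subregion in 28 of 28 rats. These levels are described and not tested, because each subregion's table was normalized separately.

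The first comparison asked which genes differed between 5 and 12 months on average over the 3 subregions. AABR07001734.1, a gene model without a name, rose by 2.24 ± 0.13 on the log2 scale (SE, 12 young and 16 middle-aged rats; limma, adjusted p = 3.98e-13). Cdh1, which encodes the epithelial adhesion protein E-cadherin, rose by 1.94 ± 0.18, and Gipr, the receptor for the gut hormone GIP, by 0.85 ± 0.08. Reads of Cdh1 were few, with young means of 6.71 normalized counts in CA3 and 2.70 in the DG. Aadat, an aminotransferase that makes kynurenic acid, rose by 0.51 ± 0.05, March7, a ubiquitin ligase, by 0.42 ± 0.04, and Jhy by 0.68 ± 0.08. Gpr17, a receptor of oligodendrocyte precursors that are about to mature, changed by -0.86 ± 0.10 and Notch3, a receptor of vascular mural cells, by -0.62 ± 0.07. The matrix protein gene Fbln2 changed by -0.46 ± 0.04, the collagen chaperone gene Serpinh1 by -0.43 ± 0.05, Slc7a5, a transporter of large neutral amino acids, by -0.34 ± 0.04, and Elavl3, a neuronal RNA-binding protein gene, by -0.27 ± 0.03.

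Of 14291 genes tested on the average, 7149 changed, 3630 upward and 3519 downward. All 12 genes named above also passed in each run of animal numbers. The first run gave 2628 changed genes and the second 8304, and 2049 genes passed in each run in the same direction (961 higher and 1088 lower). In all 3 subregions 1244 genes passed, 606 higher and 636 lower throughout and 2 with mixed directions. Gipr had 1.35 ± 0.12 in CA3 and 0.89 in the DG (limma, adjusted p = 0.00212), and did not pass in CA1 (0.32, adjusted p = 0.129). In the test within rats given below, no gene passed as different between CA1 and CA3.

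**Figure D1:**
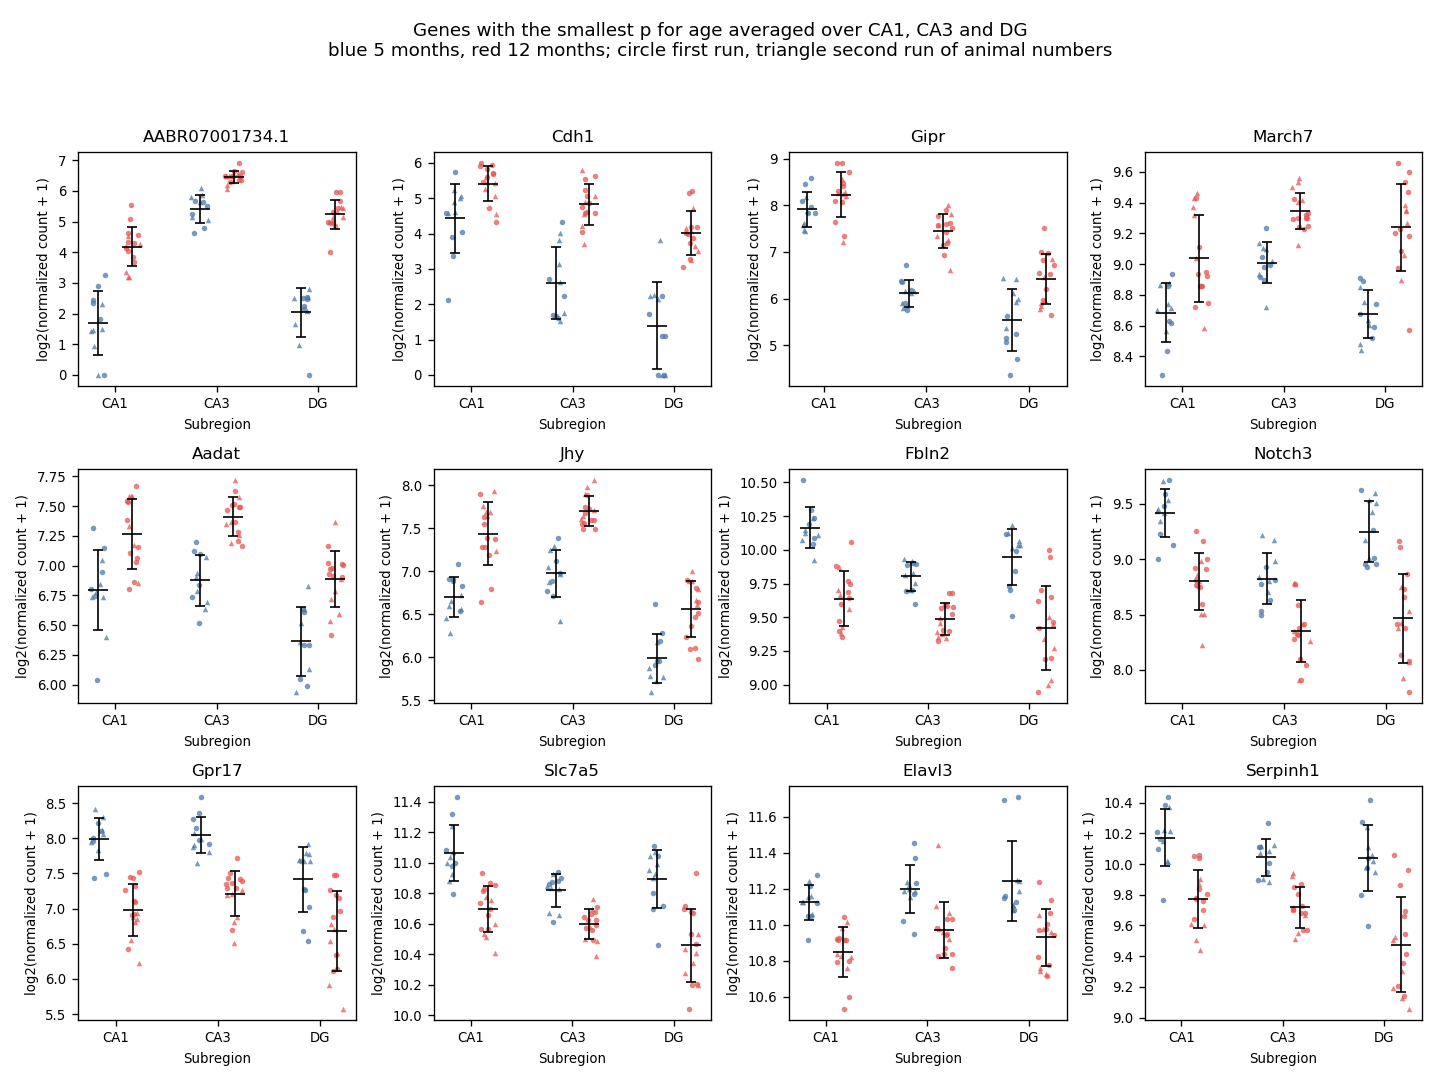
Values of the 12 genes with the smallest p for age on the average of the 3 subregions, as log2 of the normalized count plus 1 on the vertical axis, per library. Points are rats (blue 5 months, red 12 months; circles first run of animal numbers, triangles second), with the mean and SD of 12 or 16 rats in black; AABR07001734.1 in the DG differs by 3.19 between the ages.

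In CA1, the question was which genes differed with age in this subregion alone. AABR07001734.1 had 3.04 ± 2.62 normalized counts in young and 19.0 ± 9.57 in middle-aged rats (SD, n = 12 and 16), a log2 change of 2.48 ± 0.32 (SE, adjusted p = 1.43e-05). Rps15a, a protein of the small ribosomal subunit, rose from 772 ± 116 to 1426 ± 359, and Ttc14 from 255 ± 29.7 to 418 ± 79.5, changes of 0.86 ± 0.11 and 0.70 ± 0.09. Gpr17 went from 258 ± 49.7 to 129 ± 31.9, a change of -1.01 ± 0.12, and Tril, a glial partner of Toll-like receptor signalling, from 3908 ± 358 to 2928 ± 186, a change of -0.41 ± 0.05 (adjusted p = 5.88e-06). Kif26a, a kinesin family gene, changed by -0.79 ± 0.10, Mn1 by -0.73 ± 0.10, Fbln2 by -0.53 ± 0.07, Chst2, a carbohydrate sulfotransferase gene, by -0.44 ± 0.06, and F2r, a thrombin receptor gene, by -0.44 ± 0.06.

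Further upward genes of CA1 had small p values: Cep295, a centriole protein gene, rose by 0.48 ± 0.07, Tceal1 by 0.46 ± 0.07, Ngdn by 0.37 ± 0.06, LOC300249 by 0.39 ± 0.06 and Rtraf by 0.56 ± 0.09. The gene model AABR07031735.1 changed by -0.46 ± 0.06. The 16 CA1 genes with the smallest p were on the changed side of the young median in 16 of 16 middle-aged libraries. They had 1 direction in both runs, and Tceal1 missed the threshold in the first run (adjusted p = 0.052). Beyond these, the genes with the largest changes had few reads or a wide spread. B4gat1, a glycosyltransferase gene, had 113 ± 148 in young and 15.9 ± 26.6 in middle-aged rats, a change of -3.94 ± 0.74, with 7 of 16 middle-aged libraries at 0. Hprt1, a purine salvage gene, changed by -2.76 ± 0.67, Calcoco1 by -2.41 ± 0.46 and LOC100911374 by -1.66 ± 0.62. AABR07039446.1 rose by 1.55 ± 0.49, LOC108348048 by 1.55 ± 0.53, RGD1562638 by 1.42 ± 0.49 and F10, coagulation factor X, by 1.35 ± 0.37. F10 reached 249 in middle-aged replicate 10 and 27.9 in the next library, and without that rat the change was 1.11. None of these 8 genes passed in the first run (adjusted p of 0.0556 to 0.515), and 5 passed in the second. AABR07039446.1 had 0.63 in the first run and 2.75 in the second, LOC108348048 2.09 and 0.87, RGD1562638 1.74 and 1.02, and Calcoco1 -1.84 and -3.40. The call for LOC100911374 was lost in 18 of 28 fits that left out 1 rat (young replicates 1 to 6, 8, 11 and 12, middle-aged replicates 4, 5, 7, 9 and 11 to 15), with changes between -1.93 and -1.47 over all fits. The call for RGD1562638 was lost without young replicate 2, 8, 10 or 11 or middle-aged replicate 14 (1.23 to 1.65 over all fits), and that for LOC108348048 without young replicate 1, 3, 4 or 7 (1.36 to 1.79).

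In all, 3700 of 14685 genes changed with age in CA1, 1827 higher and 1873 lower. The median size of these changes was 0.30 on the log2 scale, and 237 genes changed by at least 1.5-fold. The first run alone gave 468 changed genes and the second 4958. Of the pooled calls 99.4% had 1 direction in both, which choosing them by both runs makes likely. Of the genes called from the second run's rats, 80.6% had the same direction in the first. Requiring a fold of at least 1.2 as well left 2304.

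In CA3, Gipr rose from 69.3 ± 14.8 to 180 ± 42.7 normalized counts (SD, n = 12 and 16), a log2 change of 1.35 ± 0.12 (SE, adjusted p = 1.82e-08). Cdh1 rose by 2.23 ± 0.29, Cyp2a1, a cytochrome P450 gene, by 1.95 ± 0.23 and Bpifb4 by 1.12 ± 0.15. Of these, Cdh1 and Cyp2a1 had few reads, with means from 6.71 ± 5.93 to 29.4 ± 12.0 and from 4.63 ± 2.89 to 19.5 ± 6.05. Fcgr2b, an inhibitory receptor for IgG, rose from 124 ± 17.0 to 249 ± 114. The beta-tubulin genes Tubb2b and Tubb2a changed by -0.30 ± 0.04 and -0.31 ± 0.04, Gpr17 by -0.84 ± 0.11, Ttyh3 by -0.42 ± 0.05 and Fbln2 by -0.32 ± 0.05.

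Other CA3 genes with small p were Jhy (0.73 ± 0.08) and AABR07001734.1 (1.04 ± 0.12), both higher, and Prr36 (-0.45 ± 0.06), Ubap2 (-0.39 ± 0.06) and AABR07029198.1 (-0.47 ± 0.07), all lower. Each of the 16 CA3 genes with the smallest p passed in each run. Beyond these, the largest rises were in genes of MHC class II, which present antigen, and LOC689986. RT1-Db1 rose by 2.29 ± 0.52, RT1-Da by 2.28 ± 0.48, RT1-Ba by 1.97 ± 0.45 and LOC689986 by 2.16 ± 0.51. LOC689986 had few reads, with means of 4.31 ± 9.11 in young and 20.1 ± 20.4 in middle-aged rats. The mean of RT1-Da was 34.3 ± 12.2 in young and 673 ± 2058 in middle-aged rats, with medians of 36.4 and 94.4: middle-aged replicate 10 held 8368 and the next library 728. Without that rat the changes were 1.89 for RT1-Da, 1.90 for RT1-Db1 and 1.61 for RT1-Ba, and all 3 still passed. Reads of such multigene families can be shared between members, so which member changed is uncertain. The largest falls were in AABR07030162.1 (-2.45 ± 0.76), Hprt1 (-2.38 ± 0.87), Calcoco1 (-2.0 ± 0.47) and Gpr173, an orphan receptor gene (-1.81 ± 0.62). Of these 8 genes, RT1-Db1, LOC689986 and Calcoco1 passed in the first run, where the others had adjusted p of 0.0735 to 0.319. Gpr173 also missed the threshold in the second (0.0547). RT1-Db1 had 2.70 in the first run and 1.53 in the second, Hprt1 -2.14 and -3.66, Calcoco1 -1.68 and -2.89, and Gpr173 -1.37 and -2.52. The call for Hprt1 was lost in 17 of 28 fits that left out 1 rat (young replicates 1 to 7 and 9, middle-aged replicates 7, 9 to 16), with changes between -2.83 and -2.21 over all fits. That for Gpr173 was lost in 12 (young replicates 3, 4, 7, 9 and 12, middle-aged replicates 3, 7, 8, 11, 13, 15 and 16; -2.06 to -1.60).

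In CA3, 3231 of 14893 genes changed, 1628 higher and 1603 lower, with a median size of 0.23 and 164 genes at 1.5-fold or more. The first run gave 719 and the second 2462. Of the pooled calls 99.6% had 1 direction in both, which choosing them by both runs makes likely. Of the genes called from the second run's rats, 87.1% had the same direction in the first. With a fold of at least 1.2 as well, 1224 genes remained in the count, 63.5% of them higher.

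In the DG, AABR07001734.1 rose from 3.59 ± 1.76 to 38.4 ± 12.0 normalized counts (SD, n = 12 and 16), a log2 change of 3.19 ± 0.24 (SE, adjusted p = 1.7e-10). Gabra3, the alpha-3 subunit of the GABA-A receptor, rose from 314 ± 50.6 to 539 ± 88.5 (0.77 ± 0.09). Cdh1 rose by 2.62 ± 0.35, Myo5c, a class V myosin gene, by 1.55 ± 0.21, Fcgr2b by 1.01 ± 0.14 and Gcnt1, an enzyme that branches O-glycans, by 0.88 ± 0.11. Cdh1 had few reads here, with means of 2.70 ± 3.62 in young and 16.6 ± 8.51 in middle-aged rats. Tbkbp1, which encodes a binding partner of the kinase TBK1, changed by -0.58 ± 0.07, and Gli2, a transcription factor of hedgehog signalling, from 135 ± 17.7 to 87.0 ± 14.9 (-0.64 ± 0.09). Tspan18, a tetraspanin gene, changed by -0.53 ± 0.07, Pura by -0.61 ± 0.09 and Trim8 by -0.43 ± 0.06.

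Fgl2, a fibrinogen-like protein gene, rose by 0.72 ± 0.09 in the DG and Anxa4, an annexin gene, by 0.58 ± 0.08. Faap100, of the Fanconi anaemia complex, changed by -0.50 ± 0.07, Vps37b, of the ESCRT-I sorting complex, by -0.48 ± 0.07 and Mgat5b, a glycosyltransferase gene of the brain, by -0.48 ± 0.07. The 8 upward genes with the smallest p passed in each run. Of the 8 downward ones, Tspan18 passed in the first run and the others had adjusted p of 0.068 to 0.11 there. Beyond these genes, the largest rises were in LOC102556337 (2.75 ± 0.76), Rpl35al1 (2.26 ± 0.67), LOC108351058 (2.07 ± 0.62) and Slfn4 (1.77 ± 0.41). Slfn4 had few reads, with means of 6.46 ± 5.81 in young and 17.8 ± 9.04 in middle-aged rats. The largest falls were in RGD1564887 (-3.34 ± 0.73), LOC108348044 (-2.17 ± 0.82), Gpr173 (-1.97 ± 0.61) and Hnrnpab (-1.73 ± 0.46). None of these 8 passed in the first run (adjusted p of 0.137 to 0.78), and all 8 passed in the second. LOC102556337 had 0.27 in the first run and 5.28 in the second, RGD1564887 -2.13 and -4.52, LOC108348044 -0.76 and -3.91, Gpr173 -0.72 and -3.29, and Hnrnpab -0.66 and -2.9. RGD1564887 was listed at 0 in 11 of 16 middle-aged libraries and 1 of 12 young ones. The call for LOC108348044 was lost in 11 of 28 fits that left out 1 rat (young replicates 1, 3, 7, 8 and 12, middle-aged replicates 1, 5, 7 and 12 to 14; -2.53 to -1.89 over all fits).

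In the DG, 5382 of 14526 genes changed, 2690 higher and 2692 lower, with a median size of 0.30 and 379 genes at 1.5-fold or more. The runs differed widely: 25 genes passed in the first (21 higher and 4 lower) and 6812 in the second. Of the pooled calls 97.9% had 1 direction in both, which choosing them by both runs makes likely. Of the genes called from the second run's rats, 80.5% had the same direction in the first. With a fold of at least 1.2 as well, the count was 3364.

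**Figure D2:**
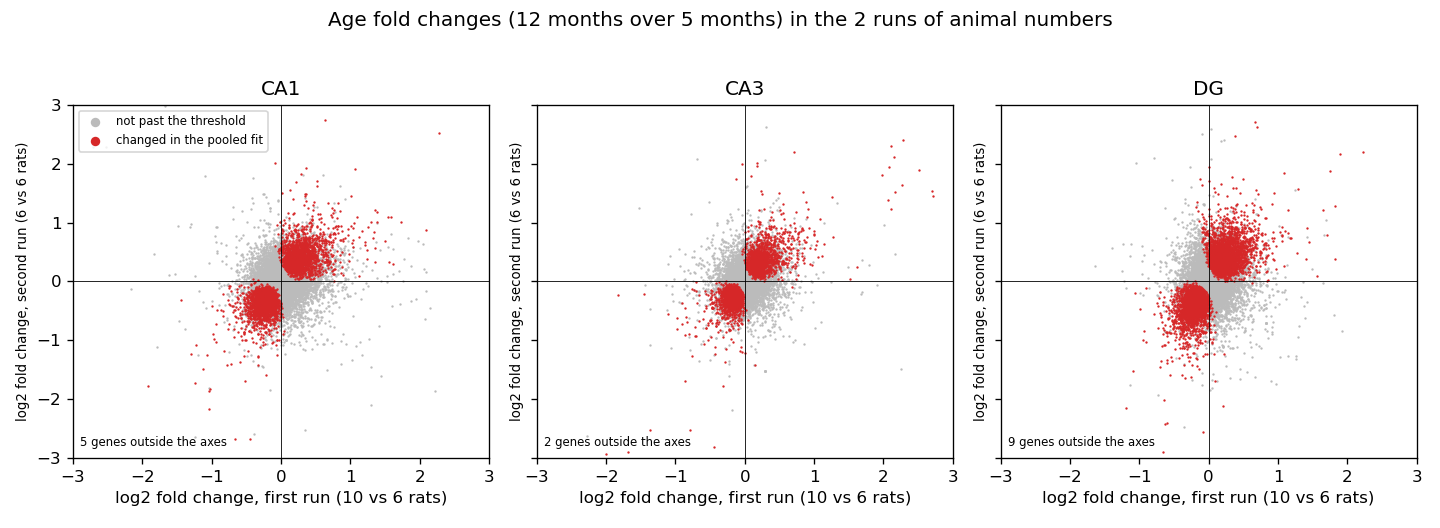
Log2 fold change with age per gene in the first run of animal numbers (horizontal axis, 10 against 6 rats) and in the second (vertical axis, 6 against 6 rats), per subregion. Red points passed the pooled test; the correlation across genes was 0.39 in CA1, 0.43 in CA3 and 0.42 in the DG.

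Across all genes, the fold changes of the runs had Pearson correlations of 0.39 in CA1, 0.43 in CA3 and 0.42 in the DG, although genes are not independent replicates. Age was permuted 100 times in the first run, with the second run kept as it was. The permutation p values were 0.0495 in CA1, 0.0099 in CA3 and 0.119 in the DG. In the DG a correlation this high was thus not rare without an age effect in the first run. Of the genes past the pooled test, some had an unadjusted p under 0.05 in both runs with the same direction. They were 1671 in CA1, 1521 in CA3 and 1885 in the DG. By chance about 18 of all tested genes would show this, if genes were independent and without the pooled test, so the sets are unlike.

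The next question was which groups of genes moved together. Of 33 gene lists fixed in advance, 32 had at least 5 tested genes in every subregion, giving 96 tests. The planned test, camera with a preset correlation of 0.01, called 31 of the 96, 11 up and 20 down, 16 of them in CA1, 10 in CA3 and 5 in the DG. That number does not stand apart from chance: 26 of 100 splits of the same rats, the real one included, gave at least 31 calls, the median of the other splits was 25 and the highest 42. With the correlation estimated from the data, 0 lists passed (lowest adjusted p = 0.115; 5 at an unadjusted p under 0.05), and fry called 34. A further test, added after these counts were seen, permuted age over rats for the mean of each list relative to all tested genes. It called 46 of 96, 15 up and 31 down, among them 29 of camera's 31, and 14 of the 46 had an exact permutation p under 0.05 in each run. Below, a list is said to rise or fall where both camera and the permutation of rats called it, and any list called by 1 of them is named as such. The first of these groups holds 29 calls, of which 15 had an exact permutation p under 0.05 in the first run, 25 in the second and 11 in both. The run values of a list are its mean change relative to all tested genes in the first and in the second run, with the exact permutation p where it was 0.05 or more. Counts of members use the test over all genes, with the count adjusted over the list alone beside it. Of the called members that the naming rule took from the lists, 27 of 106 also passed in the first run in CA1, 31 of 98 in CA3 and 3 of 111 in the DG, and 92, 68 and 100 in the second. The direction was 1 in both runs for 106, 97 and 108 of them, which choosing them by the pooled test makes likely.

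**Figure D3:**
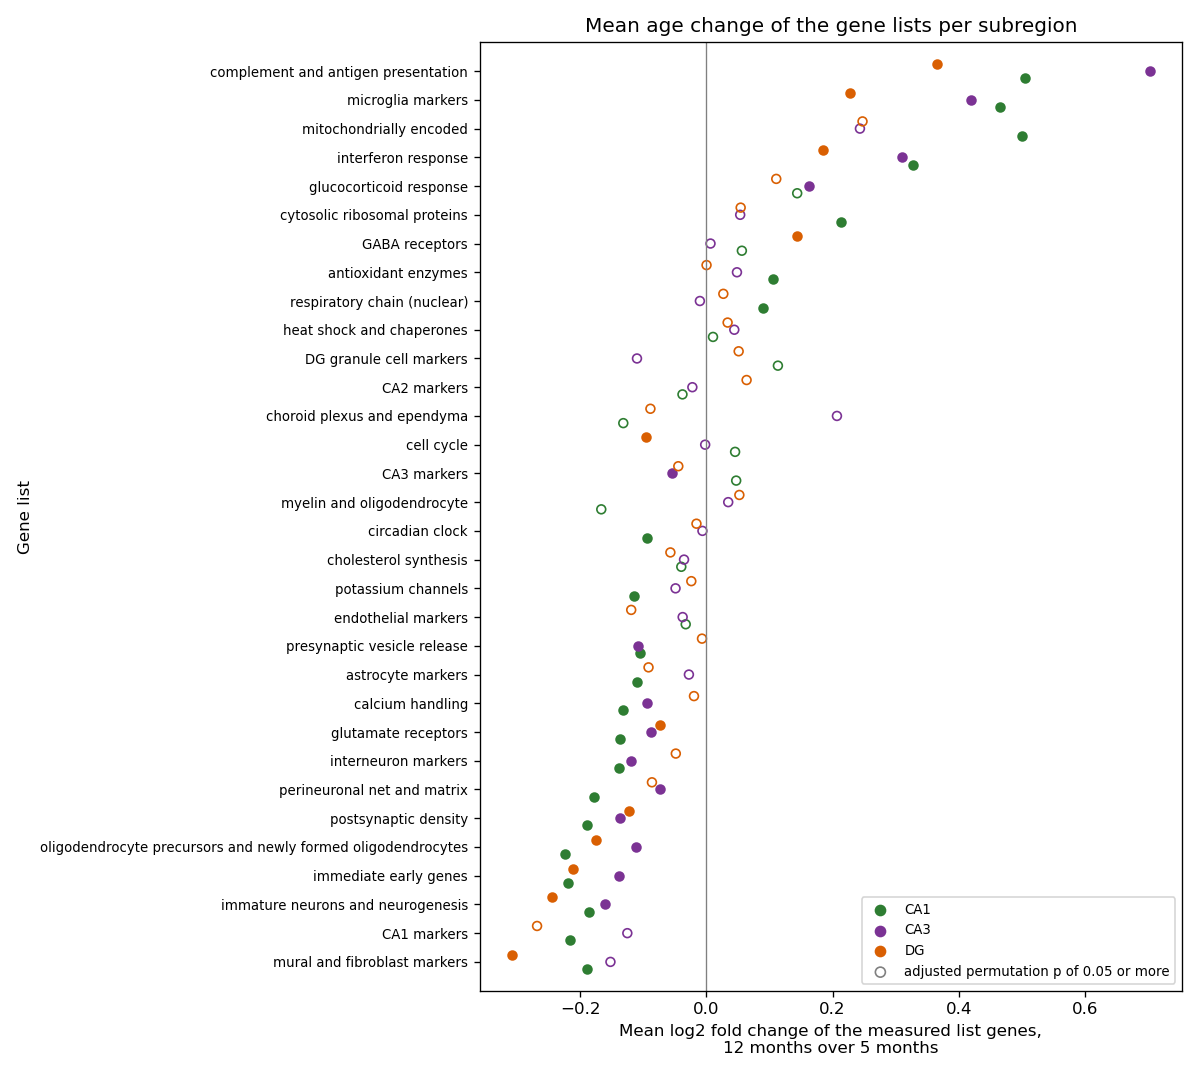
Mean log2 fold change with age of the measured members of each list (horizontal axis), 1 point per subregion (green CA1, purple CA3, orange DG). Filled points have an adjusted permutation p under 0.05 over rats, a test added after the planned one; complement and antigen presentation in CA3, at 0.70, lies farthest right.

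Genes of microglia, the immune cells of the brain, rose in all 3 subregions. In CA3, 13 of 19 measured microglial genes rose and 0 fell (15 and 0 adjusted over the list alone), in CA1 11 (14) and in the DG 10 (10), with mean changes of 0.42, 0.46 and 0.23, and of 0.35, 0.36 and 0.19 without middle-aged replicate 10. Fcgr2b rose by 1.10 ± 0.20 in CA1, 0.93 ± 0.13 in CA3 and 1.01 ± 0.14 in the DG (SE, n = 12 and 16). Trem2, a microglial lipid receptor gene, rose by 0.54 ± 0.10 in CA1 and 0.41 ± 0.08 in CA3, and Ctss, a lysosomal protease gene, by 0.59 ± 0.12 in CA1 and 0.32 ± 0.09 in the DG. Relative to all tested genes, the list mean was above the young median in 16 of 16 middle-aged rats in each subregion. Adjusted permutation p was 0.00024 in CA1 and CA3 and 0.00864 in the DG. With an estimated correlation the adjusted p was 0.654 in CA1, 0.573 in CA3 and 0.654 in the DG. Run values were 0.48 and 0.39 in CA1, 0.36 and 0.44 in CA3, and 0.19 and 0.22 (exact p = 0.0658 in the first) in the DG.

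Complement and antigen presentation genes rose in CA1 and CA3, with mean changes of 0.50 and 0.70 and medians of 0.38 and 0.40. Without middle-aged replicate 10 the means were 0.28 in CA1 and 0.53 in CA3, and in the DG 0.25 against 0.36 with it (median 0.12). In CA3, 8 of 24 rose (13 adjusted over the list alone), among them complement C3, from 1201 ± 186 to 2521 ± 2042 (0.87 ± 0.18, and 0.73 without that rat, whose library held 9858 against 3989 in the next), RT1-Da and RT1-Ba. In CA1, 3 of 23 rose (0 over the list alone): B2m, the light chain of MHC class I (0.43 ± 0.14), C1r (0.34 ± 0.12) and C3 (0.65 ± 0.23). Middle-aged replicate 10 held 11490 for C3 and 11806 for B2m in CA1, against 1746 and 4524 in the next libraries, and without it C3 changed by 0.45 and B2m by 0.32. The CA1 call was lost for B2m without young replicate 1 (0.32 to 0.47 over all fits), for C3 without young replicate 2, 8 or 9 (0.45 to 0.68), and for C1r without young replicate 2, 3, 8 or 11 or middle-aged replicate 10 or 14 (0.29 to 0.38). In the DG, 4 of 23 rose (4), C3 by 0.64 ± 0.13 and B2m by 0.33 ± 0.07 among them, and the list passed the permutation of rats alone (adjusted p = 0.0483; camera 0.08). Adjusted p with an estimated correlation was 0.788 in CA1 and 0.654 in CA3. The run values of this list were 0.63 and 0.24 (exact p = 0.175 in the first) in CA1, 0.74 and 0.55 in CA3, and 0.45 and 0.17 (exact p = 0.135 in the first) in the DG. Interferon response genes rose in CA1 (5 of 23, with 5 over the list alone) and CA3 (9 of 22, with 11 over the list alone), and the DG list (6 of 23, with 5 over the list alone) passed the permutation of rats alone (adjusted p = 0.0488). The mean interferon change was 0.33 in CA1, 0.31 in CA3 and 0.19 in the DG, and 0.22, 0.24 and 0.16 without middle-aged replicate 10. Ifit3, an interferon-induced antiviral gene, rose by 0.63 ± 0.19 in CA1, 1.04 ± 0.18 in CA3 and 0.99 ± 0.31 in the DG, and Ifi44 by 0.60 ± 0.15 in CA1 and 0.60 ± 0.13 in the DG. With an estimated correlation the adjusted p was 0.68 in CA1 and 0.654 in CA3. Interferon run values were 0.39 and 0.24 (exact p = 0.0812 in the first) in CA1, 0.26 and 0.33 (exact p = 0.0975 in the first) in CA3, and 0.12 and 0.24 (exact p = 0.253 in the first) in the DG.

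Genes of immature neurons fell in all 3 subregions: 7 of 16 fell and 1 rose in CA1 (7 and 2 adjusted over the list alone), 4 of 18 fell in CA3 (4) and 9 of 16 in the DG (9). Sox11, a transcription factor of young neurons, changed by -0.99 ± 0.21 in CA1. Marcksl1 changed by -0.62 ± 0.09 in the DG and Dpysl5 by -0.43 ± 0.09 there, Dpysl3 by -0.67 ± 0.10 in CA1. The tubulin gene Tubb3, which mature neurons also express, changed by -0.34 ± 0.07, -0.24 ± 0.05 and -0.38 ± 0.08 in CA1, CA3 and the DG. Adjusted permutation p was 0.000384, 0.0395 and 0.00024, and with an estimated correlation the adjusted p was 0.231, 0.573 and 0.115. Run values were -0.21 and -0.20 in CA1, -0.21 and -0.13 (exact p = 0.314 in the second) in CA3, and -0.28 and -0.25 in the DG. In CA3 the camera call was lost without middle-aged replicate 4, middle-aged replicate 9 or young replicate 8. Cell cycle genes passed the permutation of rats in the DG alone (14 measured, mean -0.10, adjusted p = 0.0488), with run values of -0.075 and -0.16 (exact p = 0.304 in the first). There 1 member, Tyms, rose (0.23 ± 0.08, not without young replicate 2, 4, 6 or 7, 0.20 to 0.26 over all fits) and 0 fell, and over the list alone 0 passed. The CA1 list (1 of 18 higher, Pcna, 0.33 ± 0.08, with 1 over the list alone) and the CA3 list (0 of 20, with 0 over the list alone) passed neither test.

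Oligodendrocyte precursor genes fell in CA1, where 6 of 17 fell (7 adjusted over the list alone; adjusted permutation p = 0.0032; adjusted p = 0.654 with an estimated correlation). In CA3 (3 of 17 lower, with 3 over the list alone) and the DG (7 lower and 3 higher, with 9 and 4 over the list alone) the list passed the permutation of rats alone (adjusted p = 0.0483 and 0.0207). Its run values were -0.20 and -0.30 in CA1, -0.19 and -0.073 (exact p = 0.42 in the second) in CA3, and -0.034 and -0.38 (exact p = 0.698 in the first) in the DG. Beside Gpr17, the proteoglycan gene Cspg4 changed by -0.37 ± 0.07 in CA1, -0.20 ± 0.05 in CA3 and -0.44 ± 0.11 in the DG, and C1ql1 by -0.35 ± 0.09, -0.22 ± 0.07 and -0.69 ± 0.11. Myelin genes were called lower by camera alone in CA1 (6 of 22 lower and 1 higher, with 10 and 1 over the list alone; adjusted permutation p = 0.133; adjusted p = 0.766 with an estimated correlation), with Fa2h at -0.42 ± 0.10 and Cldn11 at -0.45 ± 0.12, and with run values of -0.15 and -0.20 (exact p = 0.359 and 0.119). They passed neither test in CA3 (2 higher, 1 lower, with 2 and 1 over the list alone) or in the DG (6 higher, 1 lower, with 6 and 1 over the list alone), where Ermn rose by 0.46 ± 0.09 and Aspa by 0.59 ± 0.14.

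Genes of mural cells and fibroblasts fell in CA1 (4 of 21, with 4 over the list alone) and the DG (8 of 21, with 8 lower and 1 higher over the list alone), with adjusted permutation p of 0.00864 and 0.00419 and adjusted p = 0.654 in both with an estimated correlation. The collagen genes Col1a1 and Col1a2 changed by -0.98 ± 0.20 and -1.62 ± 0.27 in the DG, and Notch3 by -0.62 ± 0.09 in CA1 and -0.78 ± 0.12 in the DG. The mural run values were -0.23 and -0.19 in CA1 and -0.27 and -0.38 in the DG. In CA3 (4 of 21 lower, with 4 over the list alone) neither test called the list. Genes of perineuronal nets and matrix fell in CA1, where 10 of 21 fell (11 over the list alone; adjusted permutation p = 0.00024; adjusted p = 0.231 with an estimated correlation), among them Ncan, neurocan (-0.39 ± 0.07), Tnc (-0.43 ± 0.08) and the protease gene Adamts4 (-0.67 ± 0.13). In CA3 (4 lower, 1 higher, with 4 and 1 over the list alone) the list passed the permutation of rats alone (0.0096), and in the DG (4 lower, 4 higher, with 4 and 4 over the list alone) it passed neither. Matrix run values were -0.16 and -0.26 in CA1 and -0.066 and -0.12 (exact p = 0.0512 in the first) in CA3. Astrocyte markers passed the permutation of rats alone in CA1 (5 of 18 lower, with 5 over the list alone; adjusted p = 0.0247), with Sox9 at -0.65 ± 0.11 and run values of -0.15 and -0.13. They passed neither test in CA3 (3 lower, 1 higher, with 3 and 1 over the list alone) or the DG (5 lower, 1 higher, with 5 and 1 over the list alone). Endothelial markers passed neither test in any subregion (2 lower and 1 higher of 17 in CA1, 0 in CA3, 5 lower and 1 higher in the DG, and the same counts over the list alone). Tie1 fell in the DG (-0.43 ± 0.09) and CA1 (-0.38 ± 0.09). Choroid plexus and ependyma genes passed neither test (0 of 12 in CA1, 1 of 12 in CA3, 0 of 7 in the DG; 0, 1 and 0 over the list alone). Of the blood list 4 genes were measured, too few for a test: Ptprc, of leukocytes and microglia, rose by 0.70 ± 0.22, 0.65 ± 0.19 and 0.58 ± 0.15.

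Postsynaptic density genes fell in all 3 subregions: 11 of 27 in CA1 (17 adjusted over the list alone), 14 in CA3 (17) and 13 in the DG (14), while 1 rose in CA3 (1) and 3 in the DG (4). Camk2a, the synaptic kinase gene, changed by -0.29 ± 0.06 in CA3, Shank1 by -0.33 ± 0.07 there, Dlgap3 by -0.48 ± 0.11 in CA1 and -0.59 ± 0.13 in the DG, and Nrgn, neurogranin, by -0.47 ± 0.09 in the DG. Adjusted permutation p was 0.0096, 0.00864 and 0.0224, and with an estimated correlation the adjusted p was 0.654, 0.654 and 0.689. The DG camera call was lost without young replicate 1. Run values were -0.21 and -0.23 in CA1, -0.10 and -0.23 (exact p = 0.0787 in the first) in CA3, and -0.13 and -0.17 (exact p = 0.0676 in the first) in the DG. Glutamate receptor genes fell in CA1 (9 of 29 lower, 2 higher, with 12 and 2 over the list alone; adjusted p = 0.654 with an estimated correlation). That camera call was lost without young replicate 3, 7, 8, 11 or 12 or middle-aged replicate 2, 9, 10 or 13. The list passed the permutation of rats alone in CA3 (5 lower, 3 higher, with 5 and 3 over the list alone) and the DG (11 lower, 6 higher, with 11 and 7 over the list alone), with adjusted p of 0.015 and 0.0143. Glutamate receptor run values were -0.068 and -0.24 (exact p = 0.411 in the first) in CA1, -0.05 and -0.17 (exact p = 0.234 in the first) in CA3, and -0.016 and -0.18 (exact p = 0.657 in the first) in the DG. Grin2d changed by -0.58 ± 0.14 in CA1 and -0.38 ± 0.07 in CA3, Cnih2, an AMPA receptor auxiliary protein, by -0.63 ± 0.11 in the DG, while Gria4 rose there by 0.39 ± 0.06. GABA receptor genes passed the permutation of rats alone in the DG (9 of 18 higher, 4 lower, with 9 and 4 over the list alone; adjusted p = 0.0158), led by Gabra3, with Nlgn2, an adhesion protein of inhibitory synapses, at -0.37 ± 0.08, and with run values of 0.13 and 0.13 (exact p = 0.0684 in the first). They passed neither test in CA1 (3 higher and 1 lower of 17, with 4 and 3 over the list alone) or CA3 (3 higher, 2 lower, with 5 and 2 over the list alone).

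Presynaptic release genes fell in CA3 (8 of 32 lower, with 8 lower and 1 higher over the list alone; adjusted p = 0.676 with an estimated correlation), with Unc13a at -0.25 ± 0.05 and Sv2a at -0.15 ± 0.04. They passed the permutation of rats alone in CA1 (5 lower, 1 higher, with 4 and 1 over the list alone; adjusted p = 0.0305), with Rab3a at -0.25 ± 0.05. Presynaptic run values were -0.10 and -0.15 (exact p = 0.143 in the first) in CA1 and -0.09 and -0.18 (exact p = 0.0934 in the first) in CA3. No call was made by either test in the DG (7 lower, 6 higher, with 12 and 7 over the list alone). Calcium handling genes fell in CA1 (10 of 39 lower, 1 higher, with 11 and 1 over the list alone) and CA3 (10 lower, 1 higher, with 11 and 2 over the list alone), with adjusted p = 0.654 in both with an estimated correlation. Calcium run values were -0.16 and -0.15 in CA1 and -0.055 and -0.18 (exact p = 0.103 in the first) in CA3. Neither test called them in the DG (10 lower, 8 higher, with 10 and 8 over the list alone). Cacna1i, a T-type calcium channel gene, changed by -0.39 ± 0.11, -0.34 ± 0.08 and -0.43 ± 0.09 in CA1, CA3 and the DG, and Calb1, calbindin, rose by 0.43 ± 0.11 in CA1. Potassium channel genes fell in CA1 (7 of 39 lower, 1 higher, with 7 and 1 over the list alone; adjusted p = 0.654 with an estimated correlation), with run values of -0.078 and -0.19 (exact p = 0.286 in the first). They passed neither test in CA3 (4 lower, 1 higher, with 4 and 1 over the list alone) or the DG (10 lower, 5 higher, with 11 and 5 over the list alone). Interneuron markers passed the permutation of rats alone in CA1 (6 of 19 lower, with 8 over the list alone; adjusted p = 0.0131) and CA3 (2 of 20 lower, with 1 over the list alone; adjusted p = 0.0126), with Calb2, calretinin, at -0.48 ± 0.11 in CA1 and Slc32a1, the vesicular GABA transporter, at -0.27 ± 0.07 in CA3. Interneuron run values were -0.14 and -0.15 (exact p = 0.0671 in the first) in CA1 and -0.12 and -0.13 (exact p = 0.0523 in the first) in CA3. No call was made by either test in the DG (2 lower, 2 higher of 19, with 1 and 0 over the list alone).

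Immediate early genes, which neuronal activity induces, fell in all 3 subregions: 13 of 31 in CA1 (16 adjusted over the list alone), 5 in CA3 (7) and 11 in the DG (13), while 1 rose in CA3 (1) and 0 in the DG (1). Egr4 changed by -0.50 ± 0.11 in CA1 and -0.54 ± 0.12 in the DG, Egr2 by -0.64 ± 0.16 in CA1 and -0.65 ± 0.18 in CA3, and Fosl2 by -0.62 ± 0.16 and -0.43 ± 0.10 in CA1 and CA3. Dusp1 rose in CA3 by 0.42 ± 0.12. Adjusted permutation p was 0.011, 0.0224 and 0.0239, and adjusted p was 0.654 in each with an estimated correlation. Run values were -0.28 and -0.21 (exact p = 0.0649 in the second) in CA1, -0.15 and -0.17 (exact p = 0.0541 in the second) in CA3, and -0.14 and -0.36 (exact p = 0.191 in the first) in the DG. Circadian clock genes passed the permutation of rats alone in CA1 (5 of 19 lower, 2 higher, with 5 and 2 over the list alone; adjusted p = 0.000686). There the list mean relative to all tested genes was below the young median in 16 of 16 middle-aged rats. Nr1d1, a repressor of the clock, changed by -0.31 ± 0.07, and run values of the list were -0.13 and -0.091. The CA3 list (1 lower, 1 higher, with 1 and 1 over the list alone) and the DG list (5 lower, 3 higher, with 5 and 3 over the list alone) passed neither test. Glucocorticoid response genes rose in CA3 (7 of 20, with 8 over the list alone; adjusted permutation p = 0.042; adjusted p = 0.654 with an estimated correlation), with Sgk1 at 0.56 ± 0.15 and Tsc22d3 at 0.27 ± 0.06. The list had run values of -0.045 and 0.35 (exact p = 0.401 in the first), and the camera call was lost without young replicate 9. In CA1 (6 higher, 1 lower, with 6 and 1 over the list alone) and the DG (4 higher, 1 lower, with 4 and 1 over the list alone) it passed neither test, and Pdk4 rose in the DG by 0.99 ± 0.15. Heat shock and chaperone genes passed neither test (3 higher and 3 lower of 30 in CA1, 3 and 2 in CA3, 8 and 7 in the DG; 3 and 3, 3 and 2, and 10 and 7 over the list alone). Hspa1a, the inducible HSP70, fell by 0.89 ± 0.20 in CA1, 0.72 ± 0.14 in CA3 and 0.86 ± 0.13 in the DG.

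Mitochondrially encoded genes rose in CA1, where 11 of 13 rose (12 adjusted over the list alone) with a mean change of 0.50, Mt-nd3 by 1.02 ± 0.18 and Mt-nd4 by 0.61 ± 0.13 (adjusted permutation p = 0.00864; adjusted p = 0.654 with an estimated correlation). Run values were 0.053 and 0.98 (exact p = 0.727 in the first). In CA3 (5 higher, with 8 over the list alone) camera alone called the list (adjusted permutation p = 0.0916; adjusted p = 0.68 with an estimated correlation), with run values of -0.061 and 0.57 (exact p = 0.44 in the first). In the DG (2 higher, with 1 over the list alone) neither test called it. Cytosolic ribosomal protein genes rose in CA1 (24 of 59 higher, 1 lower, with 28 and 1 over the list alone; adjusted p = 0.654 with an estimated correlation), Rpl21 by 0.63 ± 0.11, with run values of 0.16 and 0.27 (exact p = 0.0736 in the first). Neither test called them in CA3 (10 higher, 3 lower, with 11 and 3 over the list alone) or the DG (5 higher, 6 lower, with 2 and 3 over the list alone), where the list differed by -0.27 in the first run and 0.37 in the second. Nuclear genes of the respiratory chain passed the permutation of rats alone in CA1 (11 of 50 higher, 3 lower, with 11 and 3 over the list alone; adjusted p = 0.0395), with Uqcrc2 at 0.28 ± 0.06 and run values of 0.07 and 0.10 (exact p = 0.114 in the first). They passed neither test in CA3 (6 higher, 5 lower, with 6 and 7 over the list alone) or the DG (6 higher, 8 lower, with 4 and 7 over the list alone). Antioxidant enzyme genes passed the permutation of rats alone in CA1 (5 of 28 higher, with 3 over the list alone; adjusted p = 0.00864), with Prdx1 at 0.47 ± 0.12 and run values of 0.095 and 0.10. No call was made by either test in CA3 (6 higher, 1 lower, with 6 and 1 over the list alone) or the DG (4 higher, 5 lower, with 4 and 4 over the list alone). Cholesterol synthesis genes passed neither test (3 of 24 lower in CA1, 5 lower and 1 higher in CA3, 5 lower and 3 higher in the DG; 3, 6 and 1, and 5 and 3 over the list alone), although Fdps fell in the DG (-0.26 ± 0.05).

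CA1 marker genes fell within CA1 (3 of 10; 7 adjusted over the list alone; adjusted permutation p = 0.0201; adjusted p = 0.654 with an estimated correlation), where Gpr161 fell by 0.54 ± 0.11 and run values were -0.24 and -0.20 (exact p = 0.121 in the second). Neither test called them in CA3 (0 of 10, with 0 over the list alone) or the DG (1 lower, with 0 over the list alone). CA3 markers passed the permutation of rats alone within CA3 (1 of 13 lower, Homer3, -0.16 ± 0.06, with 0 over the list alone; adjusted p = 0.0424). The call for Homer3 was lost without young replicate 1, 2, 3 or 12 or middle-aged replicate 7 or 14 (-0.18 to -0.14 over all fits), and run values of the list were -0.059 and -0.076 (exact p = 0.142 and 0.106). These markers passed neither test in CA1 (1 higher, with 0 over the list alone) or the DG (2 higher, 4 lower, with 2 and 4 over the list alone). DG granule cell markers passed neither test in CA1 (1 of 12 higher, with 0 over the list alone), CA3 (2 lower, with 2 over the list alone) or the DG (4 higher, 3 lower, with 4 and 3 over the list alone). CA2 markers likewise passed neither test (0 of 7 in CA1, 0 of 8 in CA3, 1 of 8 lower in the DG, with 0, 0 and 1 over the list alone).

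The last comparison asked whether age effects differed between subregions, from differences within each rat. Between the DG and CA1, Igf1r, the IGF-1 receptor, had a log2 change of 0.16 ± 0.08 in the DG and -0.42 ± 0.09 in CA1, a difference of 0.58 ± 0.09 (SE, 28 rats; limma, adjusted p = 0.00375). Eya4 differed by 1.18 ± 0.19 and Caln1, a neuronal calcium-binding protein gene, by 0.81 ± 0.13, while Sdhc, a subunit of respiratory complex II, rose in CA1 by 0.23 ± 0.05 and had -0.11 ± 0.05 in the DG. Between the DG and CA3, AABR07001734.1 rose by 3.19 ± 0.24 in the DG and 1.04 ± 0.12 in CA3. Its mean went from 3.59 to 38.4 normalized counts in the DG and from 43.6 to 87.4 in CA3. The larger log2 change in the DG thus started from few counts, and the mean was higher in CA3 at both ages. Levels from these separately normalized data are described and not tested. Fut4, a fucosyltransferase gene, fell in the DG (-0.63 ± 0.09) and rose in CA3 (0.47 ± 0.14), a difference of -1.10 ± 0.13 (adjusted p = 5.11e-05). Gsk3b, a signalling kinase gene, rose in the DG (0.35 ± 0.07) with -0.10 ± 0.05 in CA3.

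The age effect differed for 87 of 14340 genes between the DG and CA1 (57 with the higher change in the DG) and for 393 of 14378 between the DG and CA3 (194 higher in the DG). It differed for 0 of 14513 between CA1 and CA3 by limma, where 1444 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0617. All 87 and all 393 differences had 1 sign in both runs, which choosing them by the pooled test over both runs makes likely. The first run alone gave 1, 1 and 57 and the second 19, 757 and 0. Leaving out 1 rat gave 17 (young replicate 5 or 11) to 374 (middle-aged replicate 3) between the DG and CA1, 115 (young replicate 11) to 896 (young replicate 2) between the DG and CA3, and 0 to 20 (young replicate 9) between CA1 and CA3. Without the rat as a block they were 8, 171 and 4, and with the rat as a random block 164 for DG against CA1 and 14 for CA1 against CA3.

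Age fold changes were correlated between subregions across genes, with Pearson's r of 0.63 between the DG and CA1, 0.60 between the DG and CA3 and 0.64 between CA1 and CA3, and Spearman's rho of 0.66, 0.63 and 0.68. Genes are not independent replicates, and the 3 libraries of a rat share its chance differences: over 100 permutations of age over rats the median r was 0.17, 0.12 and 0.15 and the highest 0.57, 0.48 and 0.57. The covariance was 0.0426, 0.0329 and 0.0328, against permuted medians of 0.00301, 0.0019 and 0.00241. The permutation p of the covariance was 0.0099 for each pair, the smallest 100 permutations can give. Between the DG and CA1, 982 genes were higher in both and 1161 lower in both, with 9 in opposite directions, where independent lists would share 339 and 346. Between the DG and CA3 the counts were 987, 979 and 19 (298 and 298 if independent), and between CA1 and CA3 830, 897 and 4 (202 and 205). Within the first run r was 0.30, 0.42 and 0.30.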

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

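The tests of the spread of the first run, of the number blocks and of gene length against differences unrelated to age were chosen only after the results were seen.

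The age effect differed between subregions by a test within rats for 87 genes between the DG and CA1 and 393 between the DG and CA3. The 24 with the smallest p, 6 per direction in each, are given as the log2 change in the DG minus that in the other subregion. Against CA1 the difference was 0.58 for Igf1r, 0.81 for Caln1, 1.18 for Eya4, 0.62 for Trim44, 0.67 for AABR07021547.1 and 0.47 for Setd7. It was -0.34 for Sdhc, -0.41 for Tyw3, -0.65 for Svbp, -0.47 for Tmem223, -0.46 for LOC300249 and -0.29 for Cox19. Against CA3 it was 2.16 for AABR07001734.1, 0.35 for Magi2, 0.49 for Bcl7a, 0.80 for AABR07026797.1, 0.46 for Hecw1 and 0.45 for Gsk3b. It was -1.10 for Fut4, -0.51 for Mrpl14, -0.49 for Nudt19, -0.44 for Oaz1, -0.48 for Jund and -0.37 for Gga2. Each had the same sign in both runs of animal numbers, which choosing them by the pooled test makes likely.

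Chance was weighed with 100 splits of the rats into 12 and 16, the real one included. For CA1, 1 split gave as many genes as the real 3700 (highest other 2), for CA3 1 (3231; 3), for the DG 1 (5382; 2053), for the average 1 (7149; 1372) and for the DG against CA3 1 (393; 134), so chance can be excluded for these. For the DG against CA1, 2 splits gave at least 87, the real one and 1 with 306, several times the real count. A count of 87 was thus rare among the splits, which argues against chance by the limit set beforehand, although 1 other split exceeded it. Whether the split with 306 reflects a structure of the samples was not tested, and 96 of the 99 other splits gave 0. For CA1 against CA3 the real count of 0 is reached by all 100 splits whatever the data (highest other 1), so the splits say nothing about chance there. For the lists 26 gave at least 31 (highest other 42), so chance cannot be excluded. A split by run of animal numbers gave 1806 genes in CA1, 975 in CA3, 1147 in the DG and 2707 on the average, with 9 lists. For differences between subregions it gave 3 for the DG against CA1, 236 for the DG against CA3, where the runs alone gave 1 and 757, and 344 for CA1 against CA3, above the real 0, where the first run alone gave 57 and the second 0.

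In the DG, 25 genes passed in the first run and 6812 in the second. Without the 3 libraries farthest from their group 45 passed in the first run. All 3 belonged to that run (young replicates 3 and 6, middle-aged replicate 6), and fewer rats make a low count likelier. The count of 45 thus leans against those libraries as the whole cause but cannot exclude them. The first-run change was 0.355 of the second-run change for genes called in the second run (0.288 to 0.429), and 0.332 (0.263 to 0.409) with genes chosen on held-out rats, a ratio added because choosing genes by the second run lowers the first, which argues against a larger spread as the whole cause. The first of these ratios was 0.377 in CA1 and 0.353 in CA3 too, where 468 and 719 genes passed in the first run, and the median residual SD was 0.24 in the first run and 0.18 in the second in the DG, 0.23 and 0.19 in CA1, and 0.17 and 0.19 in CA3, so a larger spread may contribute in the DG. A difference between the number blocks that coincide with age in the second run may contribute and cannot be told apart from age here: the exact permutation p of the first-run score along the second-run changes was 0.0784, and age stays open as well.

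Longer genes were higher at 12 months in the DG (rho of 0.275 across genes, which are not independent replicates, for the 85.5% with a known span), against 0.0295 in CA1 and 0.0848 in CA3, where the age difference of the slope on length had exact permutation p of 0.597 to 0.906 within the runs. In the DG that slope differed between ages with an exact permutation p of 0.0249 in the first run (adjusted 0.0746) and 0.00649 in the second (adjusted 0.0195). In each run the ages hold separate blocks of animal numbers, so differences between libraries unrelated to age cannot be told apart from age by these tests, although a slope higher in both runs had been taken to argue against them. With the mitochondrial percent as a covariate the slope difference was 0.108 (0.0926 to 0.120 when 1 rat was left out). Without that covariate it was 0.110, which argues against the mitochondrial share as the cause. RNA quality was not measured in the labels used, and it and age stay open.

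In CA1 the 13 mitochondrially encoded genes differed with age by 0.08 in the first run (exact permutation p = 0.611) and 0.99 in the second (exact permutation p = 0.00216). Young rats of the second run were below those of the first by -0.65 (exact permutation p = 0.00216, adjusted 0.0130), a candidate explanation being a difference between number blocks of the same age. The middle-aged rats differed between runs by 0.26 (exact permutation p = 0.0731). This was not particular to CA1: age differences in the first and second run were -0.045 and 0.58 in CA3 and -0.12 and 0.66 in the DG. Young rats of the second run differed from those of the first by -0.43 in CA3 (exact permutation p = 0.0173, adjusted 0.0416) and -0.60 in the DG (exact permutation p = 0.0584, adjusted 0.117). An effect of age beside a difference between number blocks stays open.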

How the results depend on the processing

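Leaving out the libraries farthest from their group and the permutation of rats for lists were chosen only after the results were seen. The counts of genes changed with age in CA1, CA3 and the DG and on the average stayed within 1.5 times under all alternatives other than those given here, for which the cause was not tested unless said. With a fold of at least 1.2 as well they were 2304, 1224 (63.5% higher), 3364 and 2287, since fewer genes can pass. In the first run alone they were 468, 719, 25 and 2628. On recovered reads edgeR and DESeq2 gave 3853 and 4221 in CA1, 3245 and 3456 in CA3, 5468 and 5712 in the DG, and 7313 and 7445 on the average. Without the far libraries the counts were 4456, 2795, 6180 and 6495.

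Between the DG and CA1 the 87 became 165 with a minimum of 50, 568 with array weights, 264 with a term for the run, 1 in the first run, 19 in the second, 8 without the rat, 164 with the rat as a random block and 549 without the far libraries. Between the DG and CA3 the 393 became 959 with array weights, 1 and 757 in the runs and 171 without the rat. Between CA1 and CA3 the 0 became 2 with a pseudocount of 5, 1 with a minimum of 50, 6 with array weights, 31 with a term for the run, 57 in the first run, 1 with the marker covariate, 4 without the rat, 14 with it as a random block and 2 without the far libraries. Lists called went from 31 to 0 with an estimated correlation, and the permutation of rats called 46. In the first run the correlations of the age effects were 0.303, 0.420 and 0.300.

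In the first run alone the sign turned for Pdk4 in CA3 (-0.13) and for Mt-nd2 (-0.10) and Rps27 (-0.10) in the DG. Among lists that camera called in the pooled or the first-run test, it also turned for the lists of heat shock in CA1 (-0.10), myelin (-0.10) and mitochondrially encoded (-0.0445) in CA3, for the gene list: glucocorticoid response in CA3 (-0.029), and respiratory chain (-0.11), ribosomal proteins (-0.24) and heat shock (-0.12) in the DG.

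Leaving out 1 rat gave 2860 to 4266 genes in CA1, 2649 to 3417 in CA3, 4703 to 6158 in the DG, 6647 to 7529 on the average and 31 to 38 lists. The differences ranged from 17 to 374, 115 to 896 and 0 to 20. For the DG and CA1 the count was over 1.5 times higher without young replicate 1 (207), 6 (160) or 7 (181) or middle-aged replicate 3 (374) or 6 (185). It was lower without young replicate 3 (28), 4 (20), 5 (17), 11 (17) or 12 (57) or middle-aged replicate 2 (53), 4 (33), 5 (36), 8 (56), 9 (35), 10 (23), 11 (34), 13 (30), 14 (28), 15 (34) or 16 (49). For the DG and CA3 it was higher without young replicate 1 (704) or 2 (896) or middle-aged replicate 6 (671), and lower without young replicate 3 (247), 5 (248), 6 (199), 7 (145), 8 (130), 9 (162) or 11 (115) or middle-aged replicate 1 (234), 5 (225), 7 (211), 8 (240), 9 (223), 10 (248), 11 (222), 13 (252), 14 (237) or 15 (247). For CA1 and CA3 it was above 0 without young replicate 2 (1), 7 (6), 8 (1) or 9 (20) or middle-aged replicate 1 (9), 2 (11), 3 (4), 7 (4), 11 (1) or 15 (7).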

Other observations

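All tests of symbol families were chosen only after the results were seen. Genes were grouped by the letters of their symbol into 79 families of at least 15 tested genes, and the average over subregions was tested with camera. The Cep family, many of whose genes encode centrosomal proteins, was called higher, with 20 of 31 genes higher and 3 lower, Cep290 at 0.43 ± 0.07 and Cep126 at 0.34 ± 0.05 (SE, 28 rats). The Zfp family of zinc finger genes was called higher, with 110 of 239 higher and 46 lower, Zfp292 at 0.36 ± 0.05 and Zfp483 at 0.28 ± 0.04. The Sema family, of semaphorins, was called lower, with 12 of 19 lower and 2 higher, Sema6a at -0.32 ± 0.05 and Sema4d at -0.27 ± 0.04. The Bcl family (11 of 16 lower, 0 higher) and the Slc family of transporters (100 of 258 lower, 40 higher) were called lower, with Bcl9l at -0.44 ± 0.07 and Slc29a4 at -0.46 ± 0.06. The mean changes in the first and the second run were 0.091 and 0.22 for Cep, 0.067 and 0.15 for Zfp, -0.047 and -0.23 for Sema, -0.13 and -0.25 for Bcl, and -0.0086 and -0.12 for Slc. None of the 5 passed with an estimated correlation (adjusted p = 0.807 with an estimated correlation for each), and camera called a median of 25 of 96 gene lists in other splits of the same rats.

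Rats of the same age differed between the runs of animal numbers in 2666 genes in young CA1, 639 in young CA3 and 2055 in the young DG. In middle-aged rats 938 differed in CA1, 1055 in CA3 and 97 in the DG.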
